A study of Mus musculus with 2 samples.

How the data were processed

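Total RNA was extracted from mammary glands of C57BL/6 mice at postnatal week 6, 1 wild-type and 1 ILN/ILN sample, per the labels' protocols. Polyadenylated RNA was selected, fragmented by heat and copied with random hexamers. The second strand was made with dUTP and removed with uracil-DNA glycosylase, fragments of about 200 bp were kept, and each sample was run on 2 lanes of an Illumina GAIIx. The submitters' processing notes name Bowtie 0.12.3, TopHat 1.4.1, bedtools and the mouse build mm9, with no role or order. The program that made the gene tables, its annotation, its filters, its use of strand and its treatment of reads that match several places are not given in the sources used here.

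The authors deposited 1 gene table per sample with 21113 rows. Per the file headers the main column is an FPKM-like value, scaled for gene length and library size. In the deposited files it equals a signal per kilobase divided by 1 constant per library, 48.6 for wild type and 45.2 for ILN/ILN in units of 1000000. A further deposited column holds log2(value + 1) of the FPKM-like value, to the decimals printed. The deposited signal per kilobase comes as 3 columns, and the final one was the larger of an original and a derived estimate in all 21113 rows of both files. The original estimate times the deposited gene length was a whole number, within 0.01, in 100% of genes with a value above 0. This number is called fragments here, although whether it holds single reads or read pairs is not given in the sources used here. In 934 genes per library the value came from the derived estimate alone, and in 362 genes the libraries used different estimates. The length was below the authors' limit in 38 genes, and the shortest length was 50 bases. Because the final value takes the larger estimate, a gene with several isoforms can differ between libraries when its fragments do not.

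Depth differed little. The sum of fragments was 46133338 in the wild-type and 42953129 in the ILN/ILN library. The limit that a count of 0 allows is 3 fragments, which is 0.0618 and 0.0664 per 1000000 of each library total. Intervals for ratios are exact conditional (Clopper-Pearson) 95% intervals on the fragments of a gene, scaled by the library totals. They cover counting error alone, since sequenced fragments without molecular identifiers are not independent molecules. Folds with intervals are ratios of fragments scaled by the library totals, while log2 ratios are log2((ILN/ILN value + 1)/(wild-type value + 1)) on the deposited values, which understates the difference of low genes.

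With 1 library per genotype no test, p-value or standard error was computed. Genes counted as measured had a value of at least 1 in either library, and genes past a 2-fold ratio of (value + 1) were counted each way. For each of 33 gene lists, written before the data were examined, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. The lists cover mammary epithelium, fat, immune and other cell types that a dissected gland can hold, matrix and signalling genes, reported targets and neighbours of the locus. Genes were named by size. Among genes with a value of at least 5 in either library the 12 highest and 12 lowest log2 ratios were taken, leaving out predicted, clone-named and small RNA genes. From each list up to 4 measured members with the largest absolute log2 ratio could be named, besides all neighbours and reported targets. Values of some single genes that the rule allows are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

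The build of the submitters' processing (mm9) differs from the reference used here (GRCm38), so no coordinates are given. The reference served for gene symbols, for which genes neighbour each other and for 3′ untranslated regions, and 20931 of 21113 gene identifiers matched it. Sites for the seed were searched in the longest annotated 3′ untranslated region of each gene, in 98.0% of measured genes. Genes without such a region counted as not searched.

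The steps were tested on simulated data drawn from the real fragments of 10654 genes. Of 100 genes with a simulated 4-fold change 97 passed 2-fold, of 100 with an exact 2-fold change 10 did, since the pseudocount pulls ratios toward 0, and of 10454 unchanged genes 2 did. Intervals covered the simulated ratio in 94.0%, 99.0% and 95.5% of these genes. Of 100 random lists with no change 5 lay outside the central 95%, and of 100 lists at 1.5-fold all did. Both simulated libraries were drawn from the same means with counting error alone, and each gene was drawn independently. The simulation held no difference between animals or dissections, so these rates check the steps and are not error rates for the real libraries. Alternatives covered the pseudocount, the scaling of libraries, the expression minimum, the fold threshold, the matching of random lists and the definition of a site. Estimates from fragments alone and random lists matched on gene length were chosen after seeing the data. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.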

Results

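Polyadenylated RNA from the mammary gland of C57BL/6 mice at postnatal week 6 was profiled by strand-marked RNA sequencing in 2 libraries. One library came from a wild-type sample and 1 from a sample homozygous for the ILN allele, an insertion of an IRES-LacZ-Neo cassette at the locus of the microRNAs miR-212 and miR-132. The wild-type library held 46133338 fragments assigned to genes and the ILN/ILN library 42953129. Of 21113 genes in the table, 11354 had a value of at least 1 in the wild-type library and 11167 in the ILN/ILN library. The 10 genes with the highest share of fragments took 15.8% of the wild-type and 15.5% of the ILN/ILN fragments. Because each genotype had 1 library, no difference given here has a replicate check. Intervals in parentheses after a ratio are 95% intervals for counting error alone, and they do not cover differences between animals or dissections.

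Mir212 and Mir132 themselves were not analysed here, so the genotype labels have no check from the targeted transcripts. The first comparison asked how genes around the insertion differed between the libraries. Hic1, which encodes a transcriptional repressor and lies next to the microRNAs on chromosome 11, had a value of 6.16 in the wild-type library and 0.909 in the ILN/ILN library, with 874 and 120 fragments. It was thus 6.78-fold lower in the ILN/ILN library (5.595 to 8.27). Smg6, which encodes a nuclease of nonsense-mediated decay, lay on the same side of the microRNAs and was 1.71-fold higher (1.62 to 1.80; 8.48 against 14.5). Rtn4rl1, which encodes a Nogo receptor family member, was also 1.71-fold higher (1.59 to 1.83; 8.69 against 14.8).

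In the GRCm38 annotation the span reaching 200 kb to each side of the microRNAs held 14 genes, the microRNAs included. Of these 14, 7 had a row in the table. The other 4 measured genes had log2 ratios of (value + 1), ILN/ILN over wild type, of -0.02 for Ovca2, 0.08 for Dph1, 0.16 for Rpa1 and 0.05 for Smyd4. Smg6 overlaps Hic1 in that annotation, Ovca2 overlaps Dph1 and Rpa1 overlaps Smyd4, and whether strand was used in counting is not given in the sources used here, so these values are uncertain. Among 21 measured genes of a wider list of neighbours the median log2 ratio was 0.08, at percentile 83.9 of 10000 random lists matched on expression. On this list 5 genes differed by at least 1.5-fold, a threshold chosen after the values were seen. These were Hic1, Smg6, Rtn4rl1, Tlcd2 and Srr. Tlcd2 was at 6.11 in the wild-type and 16.5 in the ILN/ILN library, a ratio of 2.70 (2.37 to 3.08). Srr, which encodes serine racemase, was at 19.2 and 29.5, but its values did not come from fragments in both libraries. Its 1873 and 2410 fragments gave a ratio of 1.38 (1.30 to 1.47). From fragments alone 4 neighbours passed 1.5-fold, without Srr, as with each of the other scalings, and with a pseudocount of 5 in place of 1 only Hic1 and Tlcd2 did.

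**Figure D1:**
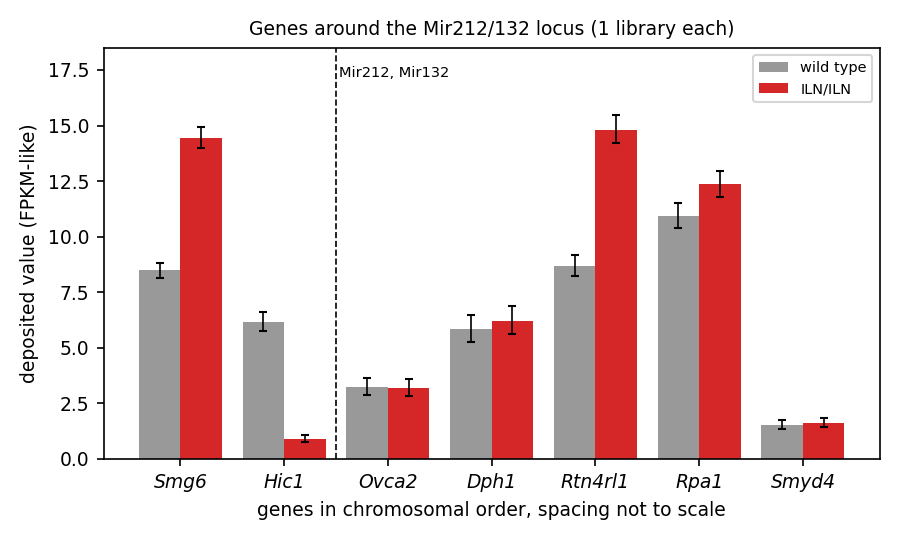
Deposited FPKM-like values (vertical axis) of the 7 measured genes within 200 kb of the microRNAs, in chromosomal order, with a grey bar for the wild-type and a red bar for the ILN/ILN library. Error bars are 95% Poisson intervals for counting error and the dashed line marks the place of the microRNAs. Hic1 was at 6.16 and 0.909, Smg6 at 8.48 and 14.5, and Rtn4rl1 at 8.69 and 14.8.

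The second comparison covered all genes. Of the 12 genes named for the lowest ratios in the ILN/ILN library, 7 were on the epithelial, lymphocyte or lymph node lists, while the 12 with the highest ratios were a mixed set with several enzymes. Aldh3a1, which encodes an aldehyde dehydrogenase, had 25 fragments in the wild-type and 1396 in the ILN/ILN library, a ratio of 60.0 (40.5 to 93.0). Glycam1, a mucin-like protein of milk and of high endothelial venules, was 29.4-fold lower (21.9 to 40.5), and Cxcl13, a chemokine that attracts B cells, was 38.2-fold lower (27.7 to 54.2). Of 11556 genes with a value of at least 1 in either library, 47 were at least 2-fold higher and 199 at least 2-fold lower in the ILN/ILN library on the log2(value + 1) scale, and 92.7% lay within 1.5-fold. The median log2 ratio was 0.02 and Pearson's r across genes was 0.984, where genes are not independent replicates. The deposited value was not made from the fragments in both libraries in 12 of the 47 higher and 25 of the 199 lower genes.

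Among the highest ratios, Cib3, which encodes a calcium-binding protein, had 9 and 227 fragments (27.1-fold; 14.0 to 60.0). Ntn1, which encodes the secreted guidance protein netrin-1, was at 7.82 and 29.2 (3.73-fold; 3.56 to 3.92). Adh7, an alcohol dehydrogenase, was at 5.46 and 20.9 (3.83-fold; 3.48 to 4.23). Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase that inactivates progesterone, was at 4.37 and 14.0 (3.21-fold; 2.77 to 3.73). Atg4c, a protease of the autophagy pathway, was at 3.82 and 12.9, and Xaf1, an interferon-inducible gene, at 6.22 and 16.7. Apol9b was at 2.06 and 7.32 and Mup11 at 54.5 and 139, and both have close paralogs with which reads could be shared. Osbpl8 and Mttp also had high ratios, with log2 values of 1.401 and 1.27. Their fragments were nearly equal in both libraries, at 478 and 470 for Osbpl8 and 282 and 274 for Mttp, and the ratios from fragments were 0.05 and 0.04 on the log2 scale.

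Among the lowest ratios, Marco, a scavenger receptor of macrophages, was at 41.3 in the wild-type and 2.07 in the ILN/ILN library (19.9-fold lower; 17.1 to 23.3). H19, an imprinted noncoding RNA, had 1187 and 39 fragments (28.3-fold lower; 20.6 to 40.0). Mrgprg, a receptor of the Mas-related family, had 873 and 5 fragments (162-fold lower; 69.4 to 502). Ngp, a granule protein of neutrophils, was at 27.3 and 2.45 (11.2-fold lower; 9.27 to 13.5). Erdr1 was at 19.4 and 1.56, with copies that reads could be shared between.

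**Figure D2:**
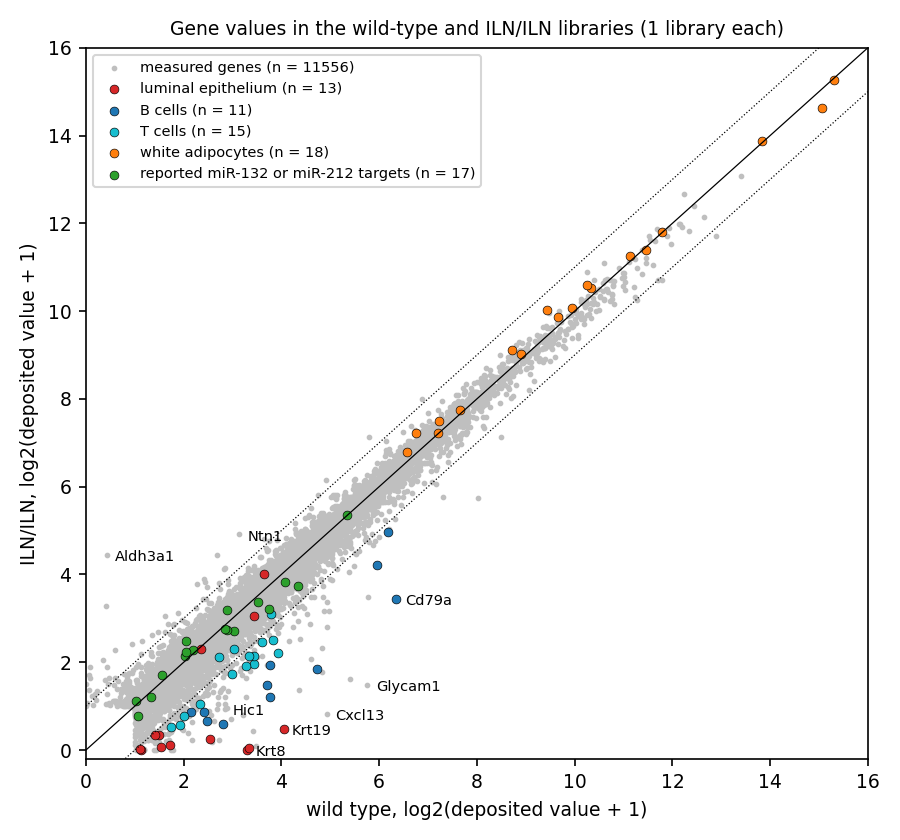
Log2(deposited value + 1) in the wild-type library (horizontal axis) against the ILN/ILN library (vertical axis) for 11556 genes, 1 library per genotype. Grey points are genes, coloured points are members of 5 gene lists, the solid line marks equal values and dotted lines mark 2-fold differences. The B cell, T cell and most luminal epithelium genes lie below the solid line, and the white adipocyte genes lie near it.

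Genes of the luminal epithelium, the milk-secreting lineage of the gland, were lower as a group in the ILN/ILN library. Of 13 measured members 10 were at least 2-fold lower and none was 2-fold higher. Krt8, a keratin of luminal cells, had 742 fragments in the wild-type and 0 in the ILN/ILN library, at least 230-fold lower with 3 fragments as the limit that a count of 0 allows. Its partner Krt18 had 583 and 2 fragments (271-fold lower; 74.8 to 2245), Krt19 had 1029 and 24 (39.9-fold lower; 26.7 to 62.6), and the secreted protein lactoferrin, encoded by Ltf, had 628 and 22 (26.6-fold lower; 17.4 to 42.7). The median log2 ratio of the list was -1.15, at percentile 0 of matched random lists. Its size depended on the pseudocount and the minimum, with -3.69 at a pseudocount of 0.1, -3.28 at a minimum of 5 and -0.37 at a pseudocount of 5. Kit, at 4.09 and 3.96, and Aldh1a3, at 11.4 and 15.04, were not lower to that extent and were chosen after their values were seen.

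Of 6 measured genes of hormone-sensing epithelium 3 were at least 2-fold lower, with a list median of -0.95 at percentile 0. Cited1, a transcriptional coregulator, had 248 and 7 fragments (33.0-fold lower; 15.8 to 82.9), Ly6d was at 53.7 and 10.2, and the growth factor gene Areg had 56 and 0 fragments. Esr1, which encodes the oestrogen receptor and was chosen after its values were seen, was at 8.90 and 11.2. With the gene at 0 set to 3 fragments the median was -0.91, and it was -2.19 and -0.27 with pseudocounts of 0.1 and 5 and -0.33 with no minimum. Genes of basal and myoepithelial cells had a median of -0.21 at percentile 3.11, inside the central 95% of random lists. It lay outside with a pseudocount of 0.1 (percentile 1.59) and with no minimum (0.06), and from fragments alone it was -0.04 at percentile 29.1. The contractile genes among them included Acta2, at 56.5 and 43.4, which vessels also express. The basal keratin genes Krt5 and Krt14 stayed under the expression minimum, with 78 and 62 fragments in the wild-type and 0 in the ILN/ILN library, at least 24.2-fold and 19.2-fold lower. They were chosen after their values were seen. Of the milk protein list only Glycam1 and Xdh were measured. Xdh, at 71.1 and 66.3, encodes xanthine oxidoreductase, and the list median of -2.19 (percentile 0.08) rests on these genes alone and was -0.05 with no minimum. Of 3 measured genes of skin keratinocytes, Krtdap had 65 and 3 fragments, Sbsn was at 45.15 and 21.2 and Calml3 at 0.762 and 1.01 (median -1.06, percentile 0.085). With no minimum the skin list had a median of 0 at percentile 51.5, inside the central 95%.

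Lymphocyte genes were lower as a group. All 11 measured B cell genes were at least 2-fold lower in the ILN/ILN library, with a median log2 ratio of -1.84 at percentile 0. Cd79a, a chain of the B cell receptor, was at 80.6 and 9.89 (8.15-fold lower; 7.47 to 8.91). Faim3 was 9.86-fold lower (8.40 to 11.6), Fcer2a 9.70-fold lower (8.08 to 11.7) and Cd22 6.77-fold lower (5.99 to 7.68). Of 15 T cell genes 12 were at least 2-fold lower, with a median of -1.27 at percentile 0. The transcription factor gene Tcf7 was 3.93-fold lower (3.50 to 4.43), Cd4 3.39-fold (3.03 to 3.80), Cd3e 3.16-fold (2.66 to 3.78) and Lef1 5.65-fold (4.22 to 7.71). Of 8 measured genes of lymph node stroma and high endothelium 3 were at least 2-fold lower, namely Glycam1, Cxcl13 and Ltb, and the median was -0.73 at percentile 0.02. Lta had 96 and 26 fragments. Plasma cell genes had a median of -0.45 at percentile 0.20, and Igj, the joining chain of secreted antibodies, was at 5.81 and 2.54. With a minimum of 5 the plasma cell median was -0.22 at percentile 15.2, inside the central 95%. With a pseudocount of 5 the medians were -1.18 for B cells, -0.71 for T cells and -0.28 for lymph node stroma, and the last was -1.48 with a pseudocount of 0.1 and -1.69 with a minimum of 5.

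Genes of myeloid and red blood cells were lower too. Of 16 macrophage and dendritic cell genes 15 had a log2 ratio below 0, with none past 2-fold and a median of -0.42 at percentile 0. The complement gene C1qc was at 537 and 295, C1qb at 718 and 468, Cd74 at 2366 and 1504 and Cd14 at 50.01 and 32.6. Of 11 neutrophil and mast cell genes 5 were at least 2-fold lower, with a median of -0.49 at percentile 0. Besides Ngp, S100a9 was at 258.8 and 52.8 (4.90-fold lower, 4.58 to 5.25), Camp at 19.9 and 4.81 and S100a8 at 7.90 and 2.51. The mast cell genes Tpsb2, Cma1, Mcpt4 and Cpa3 differed less, at 1.35-fold, 1.29-fold, 1.27-fold and 1.08-fold lower (0.881 to 1.32 for Cpa3). They were chosen after their values were seen. The 5 erythroid genes had a median of -0.99 at percentile 0. The alpha-globin genes Hba-a1 and Hba-a2, which share sequence, were 2.27-fold and 2.11-fold lower, Hbb-b1 1.99-fold (1.97 to 2.02) and Alas2, the first enzyme of haem synthesis in red cells, 1.94-fold (1.85 to 2.04). The neutrophil and mast cell median was -0.92 with a minimum of 5, and the erythroid median was -0.58 with no minimum.

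**Figure D3:**
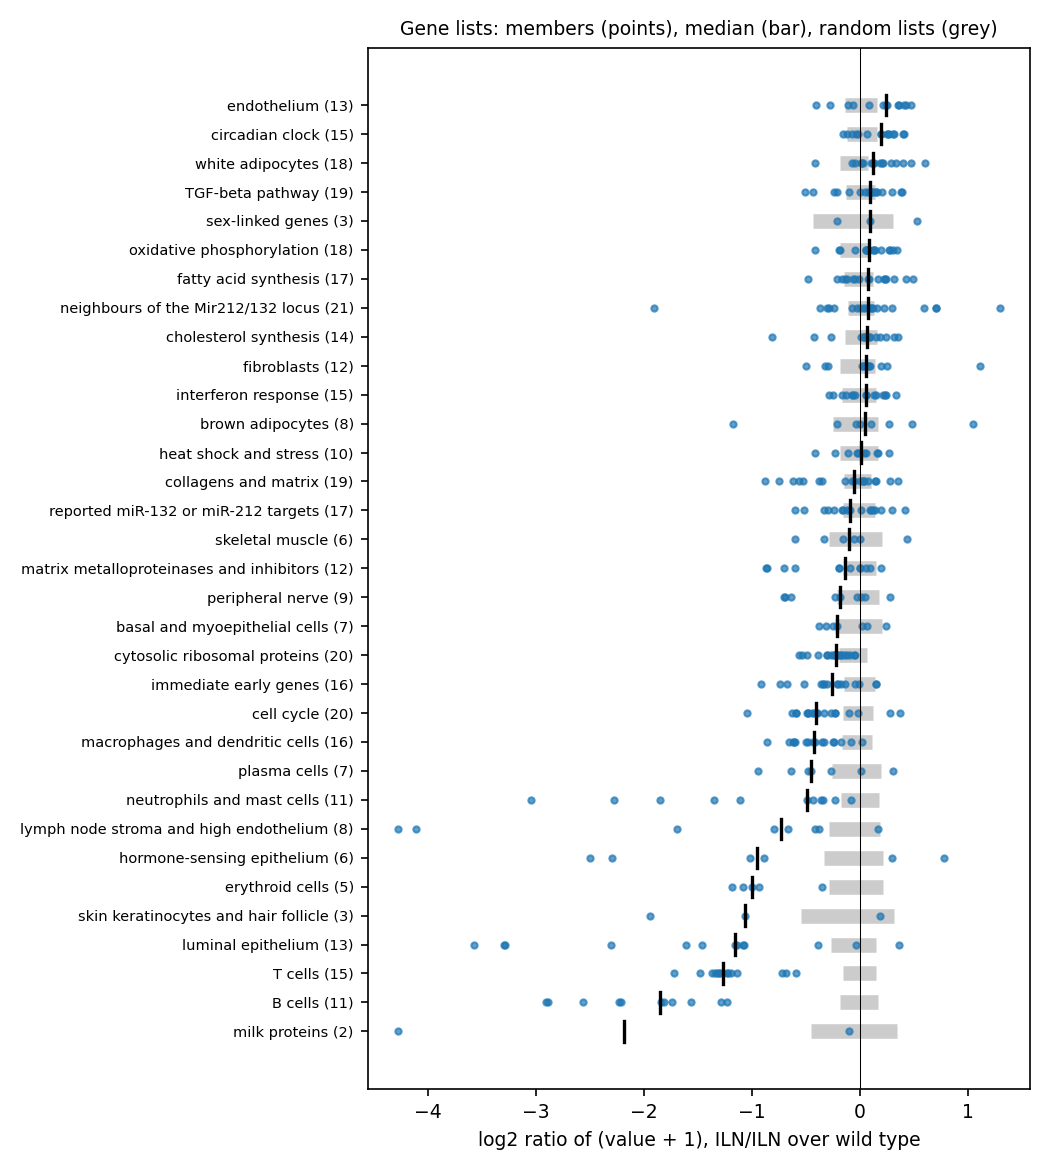
Log2 ratios of (value + 1), ILN/ILN over wild type (horizontal axis), for 33 gene lists, with the number of measured members in parentheses. Points are genes, black bars are list medians and grey bands are the central 95% of medians of 10000 random lists matched on expression. Medians run from -2.19 for milk proteins, with 2 measured genes, to 0.25 for endothelium.

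White adipocyte genes, from the main cell type of the mammary fat pad, differed little. None of 18 was past 2-fold, 15 had a log2 ratio above 0, and the median was 0.13 at percentile 99.6. Acsl1, a fatty acid activating enzyme, was at 688 and 1045, the fatty acid transporter gene Cd36 at 107 and 149, Plin1, a coat protein of lipid droplets, at 421 and 556, and Cfd, the secreted protease adipsin, at 33953 and 25466. Fatty acid synthesis genes had a median of 0.08 (percentile 90.2), with 9 of 17 above 0 and 8 below. Fads1 was at 23.8 and 34.0, Scd1, the stearoyl-CoA desaturase, at 4838 and 6511, and Acly, the ATP citrate lyase, at 385 and 276, with values not from fragments in both libraries. Cholesterol synthesis genes had a median of 0.07 (percentile 74.6). Brown adipocyte genes had a median of 0.05 (percentile 77.5), but Ucp1, the uncoupling protein of brown and beige fat, was at 59.7 and 26.0 (2.30-fold lower; 2.18 to 2.43). Ppara, a nuclear receptor of fatty acid oxidation, was 1.46-fold higher (1.38 to 1.54). Ppargc1a, a coactivator of mitochondrial genes, was at 0.509 and 2.12, values not from fragments in both libraries, and its 156 and 243 fragments gave a ratio of 1.67 (1.36 to 2.06). Oxidative phosphorylation genes had a median of 0.09 at percentile 98.0, with Cycs, which encodes cytochrome c, at 51.6 and 66.1 and Cox6c at 804 and 605. Against random lists matched on gene length as well as expression, chosen after seeing the data, white adipocytes lay at percentile 92.7 and oxidative phosphorylation at 97.1, inside the central 95%. The latter list was also inside with a minimum of 5 (97.3), with no minimum (93.8) and from fragments alone (97.4).

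Endothelial genes had a median of 0.25 at percentile 99.9, with none of 13 past 2-fold. Cdh5, the cadherin of endothelial junctions, was at 31.6 and 44.5 (1.41-fold higher; 1.36 to 1.46), Esam at 20.4 and 27.9 and Vwf, the von Willebrand factor gene, at 4.62 and 6.48, whereas the lymphatic receptor gene Flt4 was at 3.16 and 2.15. Fibroblast genes had a median of 0.06 (percentile 84.0), with 9 of 12 above 0. S100a4 was at 116.6 and 253 (2.17-fold higher; 2.07 to 2.28), whereas Pi16 was 1.41-fold lower (1.38 to 1.44), Thy1 1.25-fold (1.21 to 1.29) and Pdgfra, a receptor of platelet-derived growth factor, 1.24-fold (1.19 to 1.30). Peripheral nerve genes had a median of -0.18 (percentile 4.24), with Cnp at 30.1 and 18.2. Skeletal muscle genes had a median of -0.10 (percentile 21.9), with 4 of 6 below 0. Mylpf was at 1.94 and 0.942 and Myl1 at 37.7 and 51.4.

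Matrix genes were of interest because miR-212 and miR-132 have been studied in the stroma of the growing gland. Of 12 measured matrix metalloproteinase and inhibitor genes none was past 2-fold, and the median was -0.14 at percentile 3.48. Mmp3 was at 52.0 and 28.1 (1.85-fold lower; 1.76 to 1.95), Mmp14, a membrane-bound collagenase, at 85.9 and 46.9 (1.83-fold lower; 1.77 to 1.89), Timp1 at 10.2 and 5.88 and Mmp9, the gelatinase B gene, at 19.1 and 12.3 (1.56-fold lower; 1.47 to 1.65). Collagen and matrix genes had a median of -0.05 (percentile 30.3), with 9 above 0 and 10 below. Lox, a collagen cross-linking enzyme, was at 12.9 and 6.58, Col6a2 at 279 and 165, Col5a1 at 55.2 and 35.6 and Col6a1 at 200.1 and 135. With length matched too, the percentiles were 1.87 for metalloproteinases and 1.90 for collagens, outside the central 95%. Other settings went the other way. With no minimum the metalloproteinase median was -0.04 at percentile 18.4, and with a minimum of 5 the collagen median was -0.02 at 37.5. TGF-beta pathway genes had a median of 0.10 (percentile 90.5), with 14 of 19 above 0. Tgfb1 was at 38.3 and 26.7, Tgfbi at 90.4 and 66.8 and Smad6, an inhibitor of the pathway, at 1.81 and 2.65.

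Cell cycle genes had a median of -0.40 at percentile 0, with 18 of 20 below 0. Cdc20 was at 2.78 and 1.51 and Aurka, a mitotic kinase, at 2.15 and 1.09. Tyms, at 10.5 and 4.61, and Birc5, at 21.7 and 13.7, had values that did not come from fragments in both libraries. Their fragments, 284 and 215 for Tyms and 135 and 76 for Birc5, were 1.23-fold (1.03 to 1.48) and 1.65-fold lower (1.24 to 2.22). Immediate early genes had a median of -0.25 at percentile 0.07, with Egr3 at 1.20 and 0.165, Junb at 7.0 and 3.79 and Ier2 at 8.89 and 5.20. With a pseudocount of 5 the medians of the cell cycle and immediate early lists were -0.19 and -0.15. All 20 cytosolic ribosomal protein genes had a log2 ratio below 0, with a median of -0.22 at percentile 0.805, and Rpl18 was at 869 and 589. The values of Rps24 did not come from fragments in both libraries, and by its 25520 and 32922 fragments it was 1.39-fold higher (1.36 to 1.41), which leaves 19 of the 20 below 0. Genes also differed by length between the libraries. Across 5 groups of genes of nearly equal size, ordered from short to long, the median log2 ratio was -0.07, -0.003, 0.02, 0.04 and 0.07. Circadian clock genes had a median of 0.20 at percentile 99.4, with the repressor gene Nr1d1 at 58.2 and 77.2 and Nr1d2 at 5.37 and 7.47. Heat shock and stress genes (0.01, percentile 49.0) and interferon response genes (0.06, percentile 73.9) had medians near 0. Of the 33 lists 14 lay below and 4 above the central 95% of random lists. By chance 1.65 would lie outside if genes varied independently. Genes of a cell type can vary together and some, such as Glycam1, are on 2 lists, so no excess over chance is read from these counts. Percentiles are a description of these libraries and not a test of the genotype.

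The third comparison asked whether targets of the microRNAs differed between the libraries. None of 17 measured genes reported as targets of miR-132 or miR-212 was past 2-fold, and 8 had a log2 ratio above 0 and 9 below. The values of Sirt1 and Sox5 did not come from fragments in both libraries, and by fragments both turned direction, with ratios of 0.846 (0.687 to 1.04) for Sirt1 and 1.07 (0.840 to 1.37) for Sox5, so that 8 were again above 0 and 9 below. The median was -0.09 at percentile 9.25, and with length matched too the percentile was 2.05. With no minimum the median was -0.002 at percentile 44.1, with a minimum of 5 it was -0.16 at 3.07, and with a pseudocount of 5 -0.04 at 13.1. Mmp9 and Btg2, an antiproliferative gene at 12.3 and 8.33, had the lowest ratios, at -0.60 and -0.52. Irak4, a kinase of Toll-like receptor signalling, was at 7.22 and 5.54 and Foxo1 at 15.9 and 13.3. Sirt1 was at 3.16 and 4.57 and Sox5 at 1.505 and 1.31. Among targets with values from fragments the highest ratio was that of Zeb2, a zinc finger repressor, at 6.40 and 8.10 (1.27-fold higher; 1.20 to 1.33). Arhgap32 was at 3.55 and 3.89.

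Genes with a site for the seed shared by both microRNAs (GACTGTT in the 3′ untranslated region) were next set against genes with none. Of 11326 measured genes with an annotated 3′ untranslated region, 1493 had a site and 9833 had none. Genes with a site had a median log2 ratio of 0.05 and the others 0.009, a shift of 0.04. That median was at percentile 100 of random lists matched on expression, but genes with 8-base sites lay at 96.4 and genes with 2 or more sites at 97.2, inside the central 95%. However, 66 of 100 control heptamers with the same base composition gave a shift at least as large, with a median of 0.04 and a range from 0.0005 to 0.07. The untranslated regions with a site were longer, with a median length of 2441 against 1162 bases. Against random lists matched on expression and length of that region, the median of genes with a site was 0.0024 higher, at percentile 66.7. These lists could also draw genes with a site, so this difference is not the same measure as the shift.

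Sex-linked transcripts were examined because the labels give no sex. Xist, the noncoding RNA of the inactive X chromosome, had 0 fragments in the wild-type and 1 in the ILN/ILN library. The Y-linked genes Kdm5d, with 513 and 527 fragments, Ddx3y, with 714 and 1049, Eif2s3y, with 179 and 133, and Uty, with 95 and 109, were found in both. Y-linked transcripts with nearly no Xist mark both samples as male tissue. The list of sex-linked genes had a median of 0.10 (percentile 72.5) over 3 measured genes.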

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

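The estimate from fragments alone, the random lists matched on gene length, the lymph node list without some members, the 1.5-fold count of locus neighbours under every setting and the recounts of list members above and below 0 were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each genotype had 1 library and the labels give no replicate numbers. None of 144 recomputed values of named genes changed sign, but most could not. A pseudocount cannot turn a sign, and the scalings moved log2 ratios by only about 0.02. With the estimate from fragments, which could turn a sign, Osbpl8 went from 1.401 to 0.05 and Mttp from 1.27 to 0.04. Of 146 recomputed medians of lists outside the central 95%, 0 changed sign and 5 came inside, from the plasma cell, skin and oxidative phosphorylation lists. Of 120 recomputed medians of the other lists, 4 changed sign: heat shock and stress went from 0.01 to -0.01 with median centring, -0.0025 with upper quartile scaling and -0.0024 with the trimmed mean, and skeletal muscle from -0.10 to 0.002 with a minimum of 5. The basal and myoepithelial list went outside in 2 cases. These counts leave out the settings that changed only the random lists. With gene length matched too, white adipocytes (percentile 92.7) and oxidative phosphorylation (97.1) came inside the central 95%. Metalloproteinases (1.87), collagens (1.90) and reported targets (2.05) then went outside. In all, 51 of 266 medians moved beyond counting error and 42 by over 1.5 times, among them luminal epithelium, from -3.69 to -0.37. Scaling by upper quartile, trimmed mean or median centring moved log2 ratios by -0.01, -0.01 and -0.02. From 47 genes at least 2-fold higher and 199 lower, the counts went to 100 and 376 with a pseudocount of 0.1, 9 and 50 with a pseudocount of 5, 26 and 115 with a minimum of 5, 26 and 114 with a minimum of 1 in both libraries, 220 and 623 at 1.5-fold, and 2 and 26 at 4-fold. The stricter minimum and thresholds give fewer genes by construction, and the pseudocount acts on low genes. With fragments alone the counts were 37 and 181. The median of the reported targets was -0.11 with median centring, -0.16 with a minimum of 5 and -0.00187 with no minimum; the cause was not tested. Lists above the central 95% numbered 2 in place of 4 with unmatched random lists, and 2 with length matched, where lists below numbered 17 in place of 14. Locus neighbours past 1.5-fold numbered 2 in place of 5 with a pseudocount of 5, and 4 from fragments and with each other scaling. Median centring put 13 of 18 white adipocyte genes and 7 of 17 reported targets above 0, in place of 15 and 8. The shift of genes with a seed site was 0.0254 (percentile 96.4) for 8-base sites and 0.0248 with a pseudocount of 5, where the cause was not tested. By a measure other than the shift, the median of genes with a site was 0.00241 above random lists matched on expression and length of the untranslated region. Depth limits genes at a few fragments, such as Krt18 with 2 in the ILN/ILN library.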

Other observations

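In this part the percentiles of whole gene lists, the control heptamers and the matching on length of the untranslated region were planned, while their use to weigh explanations was chosen after the results were seen. The other tests were chosen after the results, namely the windows along chromosome 11, the haemoglobin comparison, the lymph node list without some members and the summed fragments of Y-linked, keratin and adhesion genes.

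The genes in this and the next paragraph were picked because of their ratios, so they are single values and say nothing of how other genes of their kind behaved. Cd209b, a lectin of lymph node and spleen macrophages, was at 158 in the wild-type and 53.8 in the ILN/ILN library (2.93-fold lower; 2.79 to 3.09). Timd4, a phosphatidylserine receptor, was 2.72-fold lower (2.52 to 2.92), Siglec1, the sialoadhesin of sinus macrophages, 1.78-fold (1.72 to 1.85) and Cd5l 4.57-fold (3.42 to 6.21). The adhesion gene Vcam1 was at 14.6 and 5.97, the alarmin gene Il33 at 5.47 and 1.08, and the eosinophil chemokine gene Ccl11 at 134 and 67.5. Lcn2, which encodes lipocalin 2, was 6.85-fold lower (5.74 to 8.23), and Wfdc2 and the desmosome gene Dsp had 75 and 165 fragments in the wild-type and 0 in the ILN/ILN library. Gpc3, a glypican, was 3.14-fold lower (2.92 to 3.38) and the heparin-binding growth factor genes Mdk and Ptn 3.65-fold (3.01 to 4.46) and 11.2-fold (8.71 to 14.7). Igf2, the imprinted neighbour of H19, was at 1.80 and 1.79 while H19 was 28.3-fold lower.

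Higher in the ILN/ILN library were Pfkfb3, a regulator of glycolysis, at 69.9 and 132 (1.88-fold; 1.85 to 1.92), Aqp7, the glycerol channel of adipocytes, at 18.4 and 31.7, and Pck1, an enzyme of glyceroneogenesis in fat, at 1211 and 1890. The genes Aplnr and Slco2a1 were at 3.20 and 6.43 and at 6.56 and 12.7. Aldh3a1, Ntn1 and Xaf1, all with values from fragments, lie on chromosome 11 between 1 and 15 Mb from the microRNAs in the GRCm38 annotation. In that span 3 of 306 measured genes (0.980%) were at least 2-fold higher, against 0.290% on other chromosomes, and 11.8% of windows of that width centred on genes of other chromosomes had as high a share. For spans reaching 5, 10 and 20 Mb that percentage of windows was 15.04%, 10.7% and 3.03%. Only windows with at least 50% as many measured genes as the span were used. Windows centred on nearby genes overlap, and the spans were examined after these genes were seen. The percentages are thus a description and not a test.

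The first pattern was the slightly higher level of genes with a seed site, a shift of 0.04. Control heptamers argue against release from the microRNAs as its whole cause, since 66 of 100 gave as large a shift. A trend with transcript length between the libraries is a candidate explanation. The median of genes with a site lay at percentile 100 of random lists matched on expression. With length of the untranslated region matched too it lay at 66.7, and was 0.00241 above the latter lists. That difference is not the same measure as the shift, because the random lists could also draw genes with a site. Whether a smaller effect of the microRNAs lies under such a trend stays open.

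The second pattern was the lower level of lymphocyte transcripts. For the B cell genes, less blood in the ILN/ILN tissue as the whole cause is argued against by their fragments. Their median log2 ratio of fragments was -2.76 and upper quartile -2.12, below the lowest of 3 haemoglobin genes and Alas2 at -1.18. The T cell median was -1.71, nearer to the haemoglobin genes and Alas2, which ran from -1.18 to -0.957. No quartile of the T cell genes was set against them, so less blood stays open for T cell transcripts. Less lymph node tissue in the dissected sample is a candidate explanation, since lymph node stroma genes lay at percentile 0.02 of matched random lists. Fibroblast genes, with S100a4 2.17-fold higher but Pi16 1.41-fold lower among them, lay at 84.0 and white adipocyte genes at 99.6. A low percentile was not particular to lymph node genes, however. The neutrophil and mast cell, macrophage and dendritic cell, erythroid and luminal epithelium lists lay at percentile 0. Lymphocytes themselves express Ltb, Lta and Tnfrsf4 of the lymph node stroma list, and Glycam1 is also on the milk protein list. Without the first 3 the list lay at percentile 0.09, and without all 4 at 0.55. The measured genes then left were Cxcl13, 38.2-fold lower, Madcam1, 3.02-fold lower (1.91 to 4.93), Ccl19, 1.36-fold lower (1.17 to 1.58), and Cr1l, at a log2 ratio of 0.17. Madcam1, Ccl19 and Cr1l were named after their values were seen. An effect of the genotype on lymphoid cells cannot be told apart from a difference between dissections with 1 library per genotype.

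The third pattern was the small amount of transcripts of epithelial keratin and adhesion genes. The 4 luminal keratins Krt7, Krt8, Krt18 and Krt19 had 2526 fragments in the wild-type and 32 in the ILN/ILN library. The 5 adhesion genes Epcam, Cdh1, Cldn3, Cldn4 and Cldn7 had 619 and 27. Both sets were picked from the luminal epithelium list after values were seen and have no percentile of their own. Other genes on the epithelial lists, such as Kit, Aldh1a3 and Esr1, did not go with this pattern. Whether their transcripts came from epithelial cells or from other cells of the gland was not tested, so they do not show that epithelium was kept. A difference in sex between the libraries is argued against by Y-linked and Xist transcripts. The 4 Y-linked genes had 1501 fragments in the wild-type and 1818 in the ILN/ILN library, and Xist had 0 and 1. These values show male tissue in both libraries, which may account for the low level in both. Less epithelium in the ILN/ILN sample stays open for the difference. The basal and myoepithelial list lay at percentile 3.11, inside the central 95%, but its median cannot decide this. The basal keratin genes stayed under the expression minimum, and the measured members included contractile genes such as Acta2, which vessels also express. Within that list Krt5, Krt14 and Krt17, picked after their values were seen, had 199 fragments together in the wild-type and 0 in the ILN/ILN library, while Trp63 had 147 and 109 (1.26-fold lower; 0.973 to 1.62). An effect of the genotype on the epithelium and less epithelium in the dissected piece cannot be told apart with 1 library per genotype.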
